A study of Mus musculus with 2 samples.

How the data were processed

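RNA from the olfactory bulb of 1 control and 1 odor-enriched mouse was labelled with Cy3 and hybridized to 1 Agilent mouse array each. Per the file headers, the signals were extracted with Agilent Feature Extraction 11.5.1.1, and the processed signal of each spot is an intensity after background subtraction and detrending within the array, not normalized between arrays. The deposited series matrix holds log2 values, found from the values to equal the log2 of each probe's processed signal minus 1 constant per array. The origin of that constant and the centring it reflects are not given in the sources used here, and the matrix medians are -9.48 for the control and -8.98 for the odor-enriched sample, so the matrix served only as an alternative. Probe coordinates are those of the files, on mm9.

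The groups, the comparison, the gene lists, the naming rule and all alternatives except those marked otherwise were set before the data were examined. Spots flagged as outliers (122 in the control and 183 in the odor-enriched array) were left out, and no spot was saturated. The log2 processed signals of a probe's remaining spots were averaged, and the 75th percentile over the array's probes was subtracted. That percentile was 7.966 log2 units in the control and 7.655 in the odor-enriched array. Over single spots the 75th percentile of the signal was 355 and 277, above a median local background of 17 and 22. A probe was well above background where most of its spots carried the well-above-background flag. Of 56605 probes, 56593 had a usable spot on both arrays, under 37074 gene names. A gene's value was the mean over its probes well above background on both arrays, and the difference is odor enriched minus control. Genes above background on 1 array only were given a lower bound of the fold, measured against the lowest normalized signal well above background on the other array.

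Genes were counted at a 2-fold threshold. Each of 42 gene lists with at least 5 measured members was described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins. Lists outside the central 95% were said to stand apart. These percentiles describe the 2 arrays and are not tests between mice. Another 10 lists were written after the values were seen.

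The named genes were the 15 with the largest differences in each direction among genes with at least the median signal, where all measured probes differed by at least 2-fold in the same direction and the difference held after quantile and normexp normalization. Only gene symbols qualified. The rule also took the 5 genes with the largest bounds in each direction among those above background on 1 array, the 2 highest and 2 lowest members of each list, every immediate early gene and 5 reference genes. Of 35877 probes with a RefSeq accession, 32986 matched the reference gene table of GRCm38.p6, which served for names only. The name was the same for 31451 probes and another for 1535, such as Ccn1 for Cyr61, and the array's names are given.

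The alternatives were centring on the array median, the 75th percentile over detected probes, quantile normalization, cyclic loess, normexp background correction with an offset of 50, the series matrix values and keeping outlier-flagged spots. The normexp offset is added to every signal, which makes the log2 differences of dim genes smaller. Further alternatives changed the filter on dim probes, took each gene's brightest probe, used thresholds of 1.5-fold and 3-fold, took unmatched random lists or list means, and changed the flag or the bound behind genes detected on 1 array. Masking bright patches and scaling on the E1A spike-in probes were chosen after seeing the data. A patch spot was one where the median difference of the surrounding 9 by 5 spots exceeded 1.2 log2 units in size, a limit also chosen after seeing the data.

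The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The steps were tested on simulated data for the odor enriched against control comparison with 26586 genes. Of 100 genes changed by 1.5 log2 units 98 passed 2-fold, of 100 changed by 3 log2 units 100 did, and of 26371 unchanged genes 15 did (0.0569%). Over 20 simulated arrays without changed genes, 31 of 840 lists (3.69%) lay outside the central range. The simulated noise was set per probe, above the pooled SD of 0.05 between repeat spots and below that of 0.63 between probes of a gene. It kept the control array's detection flags and held no spread between mice. These rates therefore describe the simulated setting and not the 2 arrays.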

Results

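Total RNA of the olfactory bulb, the brain region that receives the axons of the nose's sensory neurons, was measured on 2 Agilent mouse expression arrays. The labels describe the tissue as neurons of the bulb but its source as the bulb, and they give no sorting step, so whole tissue was assumed. Per the labels, 1 mouse was kept under standard odor conditions (control) and 1 mouse under odor-enriched conditions, so the comparison asks which transcripts differed between a bulb with and a bulb without odor enrichment. With 1 array per group there were no replicates, no test between groups was possible, and the number of arrays limits the precision. No paired analysis was possible because the labels pair no samples, and no replicate could be left out. Each array held 62976 spots, of which 59305 were not controls and carried 56605 probes. The share of these spots well above background was 73.7% in the control sample and 67.6% in the odor-enriched sample. All differences below are odor enriched minus control, in log2 units of signal relative to the array's 75th percentile.

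Lists of interferon-stimulated, inflammatory, blood vessel and immediate early genes stood higher in the odor-enriched bulb than in the control bulb, and lists of olfactory nerve genes stood lower. Of 23872 genes measured on both arrays, 2747 were at least 2-fold higher in the odor-enriched sample and 1317 at least 2-fold lower. A further 449 genes were well above background only in the odor-enriched sample, and 2701 only in the control sample. All 449 of the former and 188 of the latter had a bound of at least 2-fold, and with the positive-and-significant flag the former numbered 914. The lowest normalized signal well above background was -5.69 in the control and -4.66 in the odor-enriched array. Bounds are measured from these values, which favours genes seen only in the odor-enriched sample, so the 2 counts of bounds cannot be compared. For genes seen only in the odor-enriched sample, a bound of at least 2-fold follows almost from the gap between these values alone. Differences of at least 4 log2 units were found for 66 genes higher and 4 genes lower in the odor-enriched sample. Across genes the 2 arrays correlated with r = 0.946, where genes are not independent replicates.

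The share of the changed genes that were higher was 67.6%, and it depended on the filter for dim probes and on the scaling. With probes above background on either array the share was 57.6%, among genes of at least median signal 59.8% and with no filter 80.3%. It was 50.9% when each array was centred on its median and 88.5% with the deposited series matrix values, which moved the median of all genes by -0.17 and 0.33. Scaling on the E1A spike-in probes, chosen after seeing the data, gave 1.84% and moved that median by -1.76, so that of the gene groups described here only those with a median above 1.76 stayed higher. Repeat spots of 300 probes printed 10 times gave a pooled SD of 0.05 for the difference of single spots, while different probes of a gene differed with a pooled SD of 0.63. Both cover the arrays only and neither covers the spread between mice. Among the 8234 genes with more than 1 measured probe, all probes were at least 2-fold higher for 258 genes and at least 2-fold lower for 142.

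**Figure D1:**
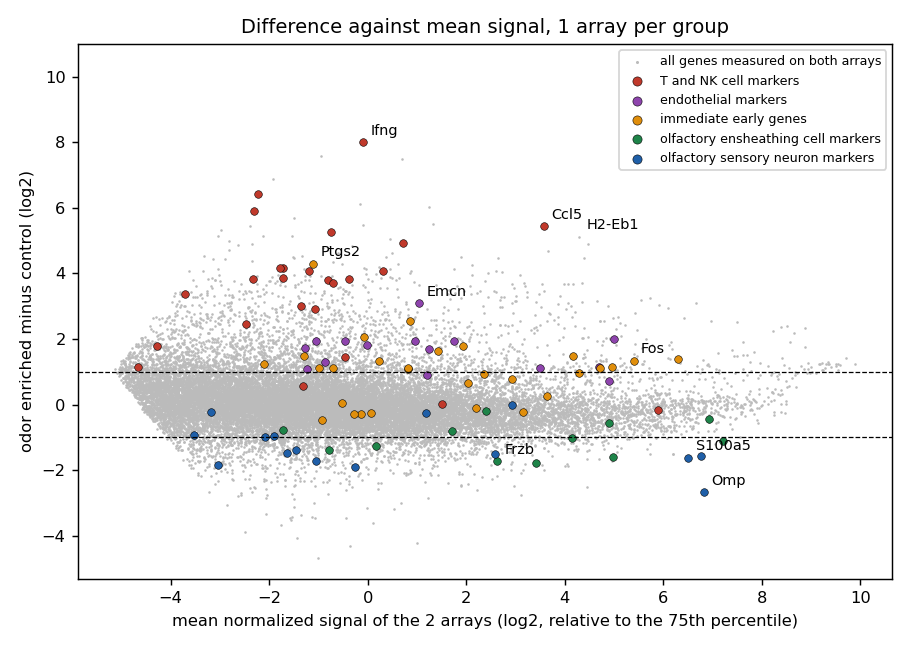
Each point is a gene measured on both arrays, with the mean normalized signal of the 2 arrays (log2) on the x axis and the difference, odor enriched minus control (log2), on the y axis. Dashed lines mark 2-fold. Ifng, a T and NK cell gene of a list chosen after the values were seen, lies highest at 8.00, and Omp, of the olfactory sensory neuron list, lies at -2.68.

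Interferon gamma and several genes known to be induced by it were higher in the odor-enriched sample. Ifng itself, the cytokine of activated T and NK cells, was 256-fold higher (8.00 log2 units; probe at chromosome 10, 117882841 to 117882900, mm9), going from -4.10 in the control to 3.91 in the odor-enriched sample. Its difference was 5.82 with normexp background correction, and from 7.83 to 8.33 under the 7 other settings run. Among the 15 genes with the largest positive differences under the naming rule were the guanylate-binding proteins Gbp11 (6.11) and Gbp4 (5.51), the protease inhibitors Serpina3g (7.49) and Serpina3f (5.48) and the chemokines Ccl5 (5.45), Cxcl1 (4.84) and Ccl8 (4.50). The same 15 held the antigen-presenting molecules H2-Eb1 (5.12) and H2-Ab1 (4.68, with 4 probes from 4.57 to 4.82), and the lymphocyte genes Cd8b1 (5.25), Nkg7 (4.94) and Cd6 (4.62). With normexp several of these differences were smaller, such as 5.97 for Serpina3g, 4.40 for Gbp11, 3.96 for Serpina3f, 3.62 for Cd8b1 and 3.48 for Cxcl1. The remaining members were C1s2 (4.62), a complement protease, and Snora74a (4.89), a small nucleolar RNA. Genes well above background only in the odor-enriched sample included Ubd, a ubiquitin-like modifier, at least 1244-fold higher, Apol7c at least 103-fold, H60b, a ligand of an NK cell receptor, at least 62.8-fold, and Ido1, a tryptophan-degrading enzyme, at least 59.9-fold. Hormad1, at least 36.6-fold higher, had its probe in a patch of the array where neighbouring spots were brighter too.

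Of the lists fixed before the data were examined, both that concern immune signalling stood above random lists of like signal. Interferon-stimulated genes had a median difference of 0.88 (percentile 99.97), with 7 of 15 at least 2-fold higher and 0 lower, such as the antiviral enzyme Rsad2 (2.17, and 1.46 with normexp). Irf9 (0.22) and Ifit3 (0.11) were lowest, and Ifit3 turned negative with median centring. Inflammatory cytokines and acute response genes had a median of 1.32 (percentile 100), with 8 of 15 at least 2-fold higher. Ptgs2, the inducible cyclooxygenase, stood at 4.30 and the chemokine Cxcl10 at 3.68, and with normexp at 2.81 and 2.68, while Lcn2 was the only member at least 2-fold lower (-1.25, and -0.91 with the series matrix values).

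A set of 10 further lists was chosen after the values were seen, so their directions are not independent evidence. T and NK cell markers had a median of 3.83, with 22 of 25 measured genes at least 2-fold higher and 2 more above background only in the odor-enriched sample. The inhibitory receptor Klrg1 stood at 6.43, and at 3.19 with normexp, whereas Cd4 (0.02) and Klrb1c (-0.18, with its probe in a bright patch) changed sign between scalings. Class II antigen-presenting genes had a median of 2.19 (8 of 10 at least 2-fold higher), class I genes 2.31 (11 of 13) and interferon-gamma-inducible GTPases and chemokines 3.0 (19 of 21), the last led by Cxcl9 (7.57, and 4.84 with normexp) and with Cxcl11 at 0.84 and Gbp9 at -0.81. Monocyte, macrophage and dendritic cell markers had a median of 0.86, with 6 of 15 at least 2-fold higher, such as Plac8 (3.21). B and plasma cell markers had a median of 0.68 over 7 genes (percentile 97.4), at the edge of the range of random lists, and lay above it under 4 of 13 settings. Neutrophil markers had a median of -0.80, with 3 of 10 at least 2-fold lower, though Ly6g stood at 3.03, and at 2.33 with normexp. Haemoglobin and erythroid genes had a median of 0.98 over 9 genes, such as Hbb-b1 (1.40), and lay inside the random range after quantile normalization, where Hba-a2 turned from 1.17 to -0.0097.

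Genes of olfactory sensory neurons were lower in the odor-enriched bulb. Their list had a median of -1.48 (percentile 0), with 9 of 15 measured members at least 2-fold lower and 0 higher, and 3 more above background only in the control sample. Omp, the olfactory marker protein of mature sensory neurons, stood at -2.68 (probe at chromosome 7, 105291870 to 105291929, mm9) and Nqo1 at -1.90. Kirrel2 (-0.23) and Gap43 (-0.02), a growth cone protein, were the nearest to 0 and turned positive with the series matrix values, Gap43 also with 3 other scalings. Markers of olfactory ensheathing cells, the glia that wrap the sensory axons, had a median of -1.06 (percentile 0), with 7 of 12 at least 2-fold lower, such as Sox10 (-1.80) and the Wnt antagonist Frzb (-1.73). Its members nearest to 0 were S100b (-0.44) and Serpine2 (-0.19), the latter positive with the series matrix values. Both lists kept their direction under each of 14 settings run, with medians from -1.66 to -0.76 for the sensory neurons and from -1.23 to -0.73 for the ensheathing cells.

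Odorant receptor transcripts lay inside the range of random lists. Of 1085 odorant receptor genes on the array, 207 were measured on both, with a median of 0.27 (percentile 76.9), 26 at least 2-fold higher and 5 lower, from Olfr1107 (4.71, and 1.94 with normexp) to Olfr713 (-2.15, and -0.40 with normexp). Another 174 were above background only in the control sample and 14 only in the odor-enriched sample. Of all genes, 2701 and 449 were, and 23872 were measured on both arrays. The lowest normalized signal well above background was -5.69 in the control and -4.66 in the odor-enriched array. Counts of genes seen on 1 array therefore do not by themselves show lower expression. The direction of the odorant receptors turned with the filter: the median was -0.09 with probes above background on either array. With no filter, which admits probes at background, it was 0.64 but stood below random lists (percentile 0). Under 2 other settings the list also left the random range, and its highest percentile over 14 settings was 100, above random lists. Vomeronasal receptors had a median of 0.26 over 34 genes, which also changed sign between settings. Nasal epithelium and gland markers had a median of -0.14 and a mean of 0.01 over 5 genes, with 6 more above background only in the control sample and 0 only in the odor-enriched sample. Epithelial markers, a list chosen after the values were seen, had a median of 0.17 over 8 genes, with 7 more above background only in the control sample, and turned to -0.61 when probes above background on either array were used.

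**Figure D2:**
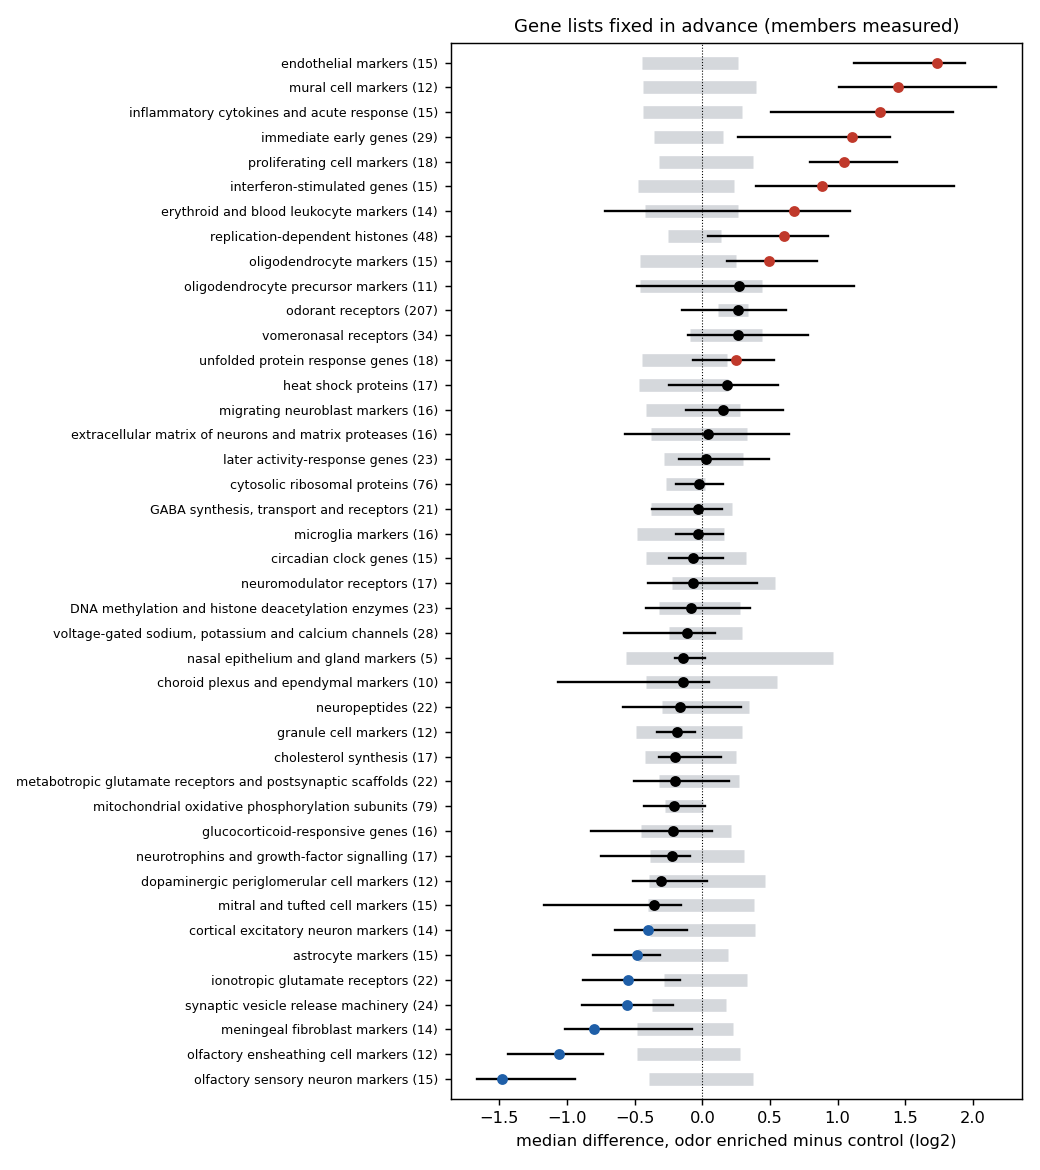
Median difference, odor enriched minus control (log2), of the 42 lists fixed before the data were examined, with the number of measured members in parentheses. Points are medians, lines run from the lower to the upper quartile, and grey bars hold the central 95% of 10000 random lists of like signal. The 10 red lists lie above the bar and the 7 blue lists below it, from endothelial markers at 1.74 to olfactory sensory neuron markers at -1.48.

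Immediate early genes, which many cells switch on within minutes of a stimulus, were higher in the odor-enriched bulb as a group. Their median was 1.11 (percentile 100), with 17 of 29 at least 2-fold higher and 0 at least 2-fold lower, and it ranged from 0.86 to 1.44 over 14 settings. Those settings leave out the E1A scaling, under which this median, being below 1.76, did not stay higher. The largest differences were those of Ptgs2 (4.30, and 2.81 with normexp), Fosl2 (2.54, with its 2 probes at 0.64 and 4.45), Cyr61 (2.06) and Egr2 (1.79). The transcription factors Fos (1.34; probe at chromosome 12, 86818118 to 86818177, mm9), Jun (1.39), Egr1 (1.13) and Nr4a1 (1.15) and the phosphatase Dusp1 (1.49) were higher too, though Egr1 (0.95) and Nr4a1 (0.98) were under 2-fold with median centring. Arc (-0.12), Npas4 (-0.28) and Egr4 (-0.26), which are induced mainly in neurons, were less than 2-fold different and turned positive with the series matrix values, Arc also with loess. Homer1 stood at -0.48 and Egr3 at 0.05, the latter negative with median centring and with normexp. The list of later activity-response genes had a median of 0.02 (percentile 57.8), which turned negative with median centring and quantile normalization, with Plk2 (2.66) and Pdyn (1.71) at one end and Kcnf1 (-1.02) and Inhba (-2.16) at the other. With normexp Pdyn (0.94) and Kcnf1 (-0.45) were under 2-fold.

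**Figure D3:**
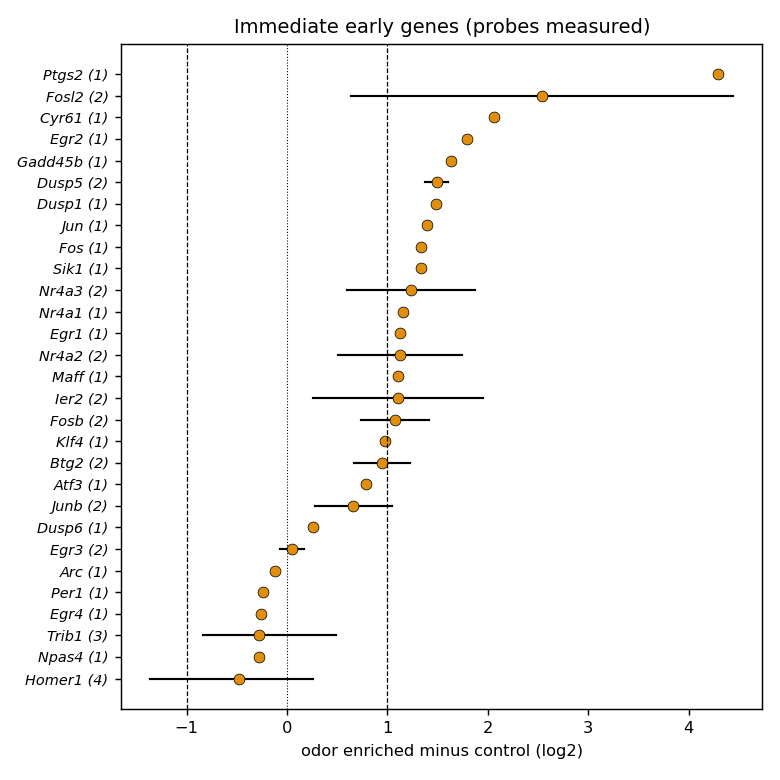
Difference, odor enriched minus control (log2), of each of the 29 immediate early genes, with the number of measured probes in parentheses. Points are means over probes, lines run from the lowest to the highest probe, and dashed lines mark 2-fold. Ptgs2 lies highest at 4.30 and Homer1 lowest at -0.48, and Fosl2 has probes at 0.64 and 4.45.

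Genes of blood vessels and of dividing cells were higher in the odor-enriched sample. Endothelial markers had a median of 1.74 (percentile 100), with 13 of 15 at least 2-fold higher, from the sialomucin Emcn (3.10) to the tight junction protein Cldn5 (0.71). Mural cell markers, of the pericytes and smooth muscle around vessels, had a median of 1.45 (9 of 12), with the potassium channel Kcnj8 at 2.56 and the smooth muscle myosin Myh11 at 2.48 over 4 probes from 0.74 to 3.38, and with normexp at 1.73 and 1.71. The pericyte genes Pdgfrb (0.29) and Vtn (-0.85) were its lowest members. Proliferating cell markers had a median of 1.05, with 10 of 18 at least 2-fold higher, such as the helicase subunit Mcm6 (2.13) and the topoisomerase Top2a (1.62, and 0.90 with normexp). Replication-dependent histones had a median of 0.60 over 48 genes, with 10 at least 2-fold higher and 2 lower, from Hist1h2ab (2.43) to Hist2h2be (-2.22). Erythroid and blood leukocyte markers had a median of 0.68 over 14 genes, but this was 0.03 after quantile normalization, inside the random range. In all, the list lay inside that range under 2 of 14 settings. T and NK cell genes were higher in the same sample, with the median of 3.83 given above.

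Among the glia and coverings of the bulb, oligodendrocyte markers were higher and astrocyte and meningeal markers lower. Oligodendrocyte markers had a median of 0.50 (percentile 99.7), with 2 of 15 at least 2-fold higher, the myelin genes Opalin (1.77) and Ermn (1.26), and lay inside the random range when the list's mean was used. Opalin stood at 0.84 with normexp and Ermn at 0.24 after quantile normalization, each under 2-fold. Astrocyte markers had a median of -0.48 (percentile 2.45), close to the limit, and lay inside the random range under 4 of 14 settings, while the filament protein Gfap stood at -2.13 with 2 probes at -2.17 and -2.08. Meningeal fibroblast markers had a median of -0.80, with 4 of 14 at least 2-fold lower, such as Fmod (-2.08), whereas Lum stood at 0.86 and the collagen Col1a1 at 0.82. Microglia markers had a median of -0.03 and a mean of 0.05, inside the random range, and oligodendrocyte precursor markers 0.27, also inside it, with the sign of each changing between settings.

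Of the 4 lists of synaptic genes, 2 were lower in the odor-enriched sample, and those of GABA genes (-0.03) and of metabotropic glutamate receptors and scaffolds (-0.20) lay inside the random range, turning positive with the series matrix values. Ionotropic glutamate receptor genes had a median of -0.55 (percentile 0.03), with 5 of 22 at least 2-fold lower, such as Grik3 (-1.65) and Gria3 (-1.44, and -0.83 with normexp), and lay inside the random range when each gene was represented by its brightest probe. The vesicle release machinery had a median of -0.55 (percentile 0.04), with 6 of 24 at least 2-fold lower, such as Sv2b (-1.51) and Vamp2 (-1.23, and -0.90 with the series matrix values), and 1 higher, Cplx2 (1.41, and 0.81 after quantile normalization). Cortical excitatory neuron markers had a median of -0.40 and a mean of -0.13, with Neurod1 at -1.20, though at -0.090 with normexp, and lay inside the random range under 8 of 14 settings. Markers of the bulb's own neurons lay inside the random range: mitral and tufted cells had a median of -0.36 (percentile 3.76), dopaminergic periglomerular cells -0.31, granule cells -0.18 and migrating neuroblasts 0.16. Granule and dopaminergic cell markers turned positive with the series matrix values, and neuroblast markers negative with median centring. Mitral and tufted markers lay below that range under 5 of 14 settings. Within that list Doc2g (-1.84) and the glutamate transporter Slc17a7 (-1.67, and -0.66 with normexp) were lower, while Tbx21 (3.11, and 2.47 with normexp), also a transcription factor of T and NK cells, was higher.

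The genes with the largest negative differences under the naming rule had mixed known functions. They were Lhfpl1 (-4.24), the muscle-type light chain Myl10 (-3.62), the muscle protein Myoz1 (-3.45), the chemokine receptor Ccr6 (-3.19), the ciliary protein Rsph1 (-3.15), Retsat (-3.01), Plekha4 (-2.76), Fgfbp1 (-2.71), Omp, Hey2 (-2.60), Egfl8 (-2.57), Scrib (-2.50), Col9a2 (-2.50), Ctxn3 (-2.43) and Ltbp2 (-2.42). Of these, Fgfbp1 and Egfl8 were measured by 2 probes each, which all differed by at least 2-fold, and the others by 1. With normexp several were smaller, such as Myl10 (-2.85), Myoz1 (-2.42), Rsph1 (-2.48) and Fgfbp1 (-1.83). Genes above background only in the control sample included C130078N14, at least 23.7-fold higher there, Stfa1 at least 17.4-fold, Agr3 at least 10.7-fold, Acsm4 at least 10.6-fold and the protease inhibitor Spint1 at least 10.5-fold. In all, 477 genes higher and 348 genes lower met the rule's criteria.

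Stress genes were mixed. Unfolded protein response genes had a median of 0.25 (percentile 98.7), with 1 of 18 at least 2-fold higher, Trib3 (2.37, and 1.23 with normexp), and lay inside the random range under 3 of 14 settings. Heat shock genes had a median of 0.18 (percentile 97.1), inside the range, and lay above it under 5 of 14 settings. Hspa1b (4.15) and Hspa1a (3.69), the stress-inducible forms of Hsp70, were higher, while Bag3 stood at -0.83 and Hsp90aa1 at -0.47. Commonly used reference genes differed by less than 2-fold: Gapdh stood at -0.46 (7 probes from -0.75 to 0.06), Actb at 0.72, Hprt at 0.74, Ppia at 0.33 and Tbp at -0.01. Under the series matrix values Actb and Hprt passed 2-fold, while Tbp ranged from -0.19 to 0.32 and Ppia from -0.09 to 0.66 over 8 settings.

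The difference varied with signal, place on the array and the probe's position in its transcript. The median was 0.43 among the dimmest 10th of genes, where 473 were at least 2-fold higher and 24 lower, and -0.17 among the brightest 10th. Over 3942 pairs of probes of 1 transcript that start at least 500 bases apart, the difference of the downstream probe minus that of the upstream probe had a median of -0.24. Local patches covered 160 spots, in a block of 87 spots and a block of 73 spots, and the spots around each patch spot were brighter in the odor-enriched sample by a median of 1.65. Of the 99 measured genes with a probe there, 36 were at least 2-fold higher. Of the 102 probes at least 3 log2 units higher while their gene's other probes averaged under 1, 14.7% lay in a patch, compared with 0.221% of the 21298 other probes of genes with more than 1 probe above background.

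**Figure D4:**
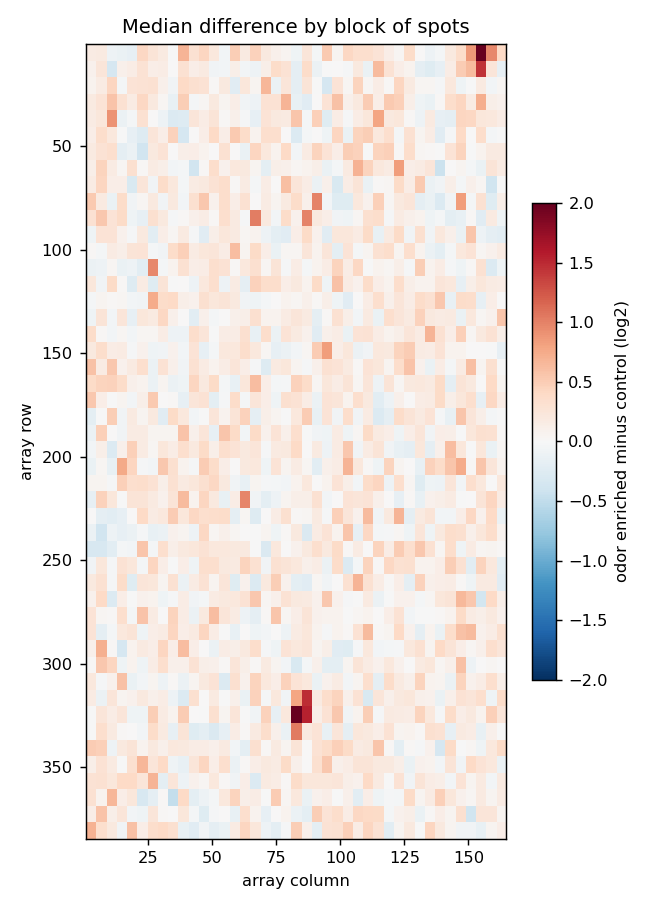
Median difference, odor enriched minus control (log2), of blocks of neighbouring spots, placed by array row and column. The dark red blocks mark the patches at rows 1 to 14, columns 151 to 164, and at rows 314 to 333, columns 82 to 87.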

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

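The spike-in control probes were examined only after the data were seen. They are designed to report RNAs added to a sample and entered the results above only in the scaling on E1A probes. Of 10 E1A probes, the 8 above background on both arrays were brighter in the odor-enriched sample by a median of 1.76 log2 units relative to the 75th percentile, from 1.53 to 4.73, and by 2.74-fold in signal before scaling. The amounts of total RNA and of spike-in RNA used for each array are not given in the sources used here, so these values and the counts scaled on E1A do not show whether total RNA differed. The probe E1A_r60_a107 had the difference of 4.73. The probe ERCC-00018_67 was higher by 3.92 and the probe ERCC-00113_271 by 3.67. The other ERCC probes above background on both arrays did not share this, with ERCC-00012_90 at 0.28 and ERCC-00148_99 at -0.093, and the rest were not above background on both. Whether ERCC RNA was added is not given in the sources used here. The values of 3.92 and 3.67 therefore cannot be read as differences of added RNA.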

How the results depend on the processing

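Scaling on E1A probes and masking bright patches were chosen only after the results were seen. Genes at least 2-fold higher and lower numbered 1256 and 622 with normexp, 4466 and 582 with the series matrix values, 374 and 19982 with E1A scaling, 9379 and 2294 with no filter on dim probes, 1065 and 715 among genes of at least median signal, 5072 and 3891 at 1.5-fold and 1286 and 330 at 3-fold. Lower genes numbered 2061 with median centring and 2380 with probes above background on either array. The filter and the threshold act through the genes they admit, and E1A scaling and the series matrix through 1 constant per array. Normexp added an offset of 50 to each signal, which makes the differences of dim genes smaller. The median processed signal was 37.6 in the control and 34.3 in the odor-enriched array. How much of the normexp change came from the offset was not tested. Genes above background only in the odor-enriched sample numbered 914 with the positive-and-significant flag, and 188 of those only in the control sample had a bound of at least 2-fold. The technical spread was 0.14 from spike-in spots. The lists outside the central range numbered from 15 to 18 over the settings, compared with 17. With no filter, probes at background enter, and many of these read higher in the odor-enriched sample after scaling. Examples not above background on either array are ERCC-00024_60 (1.07) and ERCC-00130_136 (1.06), though ERCC-00041_75 stood at 0.19. Values and counts with no filter thus carry differences of background. The odorant receptor median was 0.64, below random lists, with no filter. The epithelial median was -0.61 with either array and -0.60 with no filter, and the Hba-a2 difference -0.0097 after quantile normalization. The causes of these 3 changes were not tested further. Of the other list results, 677 kept their side, 20 lost and 23 gained a place outside the random range. Of the named gene results, 1873 kept their side of 2-fold, 101 lost it and 48 gained it. The E1A scaling enters neither the list nor the named gene tally. No test between mice and no omission of a replicate was possible with 1 array per group, and genes near background carry the least certain differences.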

Other observations

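All tests of explanations in this part were chosen only after the results were seen. Several other gene groups were measured in the bulb. Glucocorticoid-responsive genes had a median of -0.22 over 16 genes, with Fkbp5 at -1.64 and Nfkbia at 1.32. Choroid plexus and ependymal markers had a median of -0.15 over 10 genes, with the transport protein Ttr at -1.78, though at -0.84 with normexp, and the water channel Aqp1 at -1.81. Neuropeptide genes had a median of -0.17, with Cartpt at -2.15, Npy at -1.59 and Pdyn at 1.71, the last at 0.94 with normexp. Cytosolic ribosomal protein genes had a median of -0.03 over 76 genes, with 0 at least 2-fold different, and respiratory chain subunits had -0.21 over 79. Circadian clock genes had a median of -0.07 and voltage-gated channels -0.11, with Kcna2 at -1.32, though at -0.62 with normexp. Each of these 7 lists lay inside the range of random lists, though the channels lay below it under 3 of 14 settings, the respiratory chain under 2 of 14 and the choroid plexus list with its mean. Each median turned positive with the series matrix values.

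The remaining fixed lists lay inside that range too, except that metabotropic receptors and scaffolds lay below it with the brightest probe of each gene. Metabotropic glutamate receptors and postsynaptic scaffolds had a median of -0.20, with Homer3 at -1.24, though at -0.54 with normexp, and Shank2 at 1.53 over 3 probes from -0.19 to 3.92. GABA genes had a median of -0.03, with Gabrd at -1.13, though at -0.80 with the series matrix values. Neuromodulator receptors had -0.07, neurotrophin and growth-factor genes -0.23, DNA methylation and histone deacetylation enzymes -0.09, and cholesterol synthesis genes -0.20. The neuronal extracellular matrix list had a median of 0.04 and a mean of -0.01, with the protease Plat at -1.83. Each of these 7 medians changed sign between scalings.

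Interferon-inducible and T or NK cell genes were higher in the odor-enriched sample, where Ccl5 reached 6.31 from 0.86 in the control. More blood of unchanged cell composition is argued against. The T and NK median exceeded the haemoglobin median by 2.86 log2 units, while the haemoglobin genes ranged from 0.24 to 1.40. That T and NK list was written after the values were seen, and all 9 haemoglobin genes were higher. Blood richer in T and NK cells would not be told apart by this comparison, so more blood as such stays open. A bright patch is argued against, with 1 of 95 higher probes (1.05%) of these genes in a patch. More T and NK cells in the tissue stays open: without the 6 genes that led to the list, 18 of 21 (85.7%) were at least 2-fold higher or above background in that sample only, but the list was written after the values were seen, as were the B cell and neutrophil lists with 3 of 18 (16.7%). An effect of the odors, or another difference between these 2 mice, stays open and untested with 1 mouse per group.

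Olfactory sensory neuron genes were lower in the odor-enriched sample. Less olfactory nerve layer in that dissection may account for this, since ensheathing cell genes had a median of -1.06, and -1.26 over the 5 of 12 that no other list holds, though of the abundant members Fabp7 stood at -1.10 and S100b at -0.44. A bulb with less nerve layer before dissection would give the same values, so they do not single out the dissection. Nasal epithelium carried into the control dissection cannot be told apart. The median of 13 nasal and epithelial genes on both arrays was 0.02. With those on 1 array at their bound it was -0.19 over 26, a form adopted after the first value was seen. Those bounds start from the lowest signal well above background, which was higher on the odor-enriched array, so -0.19 cannot show how much lower they were. Of the 26, 13 were above background only in the control sample and 0 only in the other. Of all genes, 2701 and 449 were, and 23872 were measured on both arrays. Of odorant receptors, 174 were above background only in the control sample, 14 only in the other and 207 on both. Prom1 (2.42) and Cldn4 (1.77) were at least 2-fold higher and Cdh1 (-1.03) lower. Cldn4 fell under 2-fold in 1 of 8 settings and Cdh1 in 3. An effect of the odors on the sensory neurons was not tested.

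Immediate early genes were higher in the odor-enriched sample. Recent neuronal activity cannot be told apart: 9 neuron-restricted activity genes had a median of -0.092, but 5 of them came from the immediate early list itself and were picked after their values were seen. The list of later activity-response genes, fixed before the data were examined, had a median of 0.02 over 23 genes (percentile 57.8), inside the random range. Stress of handling stays open, since the heat shock median was 0.18 with Hspa1b at 4.15. A larger share of vessel cells stays open too, since 4 of 29 immediate early genes (13.8%) were higher by more than the endothelial median. Odor enrichment as the cause was not tested, with 1 mouse per group.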
